A study of Arabidopsis thaliana with 3 samples.

How the data were processed

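Total RNA from the aerial parts of 2-week-old Arabidopsis thaliana seedlings of accession Col-0 was measured on 3 Agilent 1-colour oligonucleotide arrays, labelled with Cy3. The labels give 1 array of wild-type plants and 1 array of each of 2 transgenic lines (4.4-1 and, separately, 4.4-5) that overexpress AtDOF4.4, a member of the DOF family of plant zinc finger transcription factors. Wild type and both lines were grown on MS medium (a mineral salt medium for plant culture), per the labels' protocols. Groups were taken from the genotype label, and the 2 lines served as the replicates of the overexpressing group. The labels do not say whether the RNA came from pooled or separate plants. The p-values therefore measure only the spread between the 2 lines, which may be biological or technical, and the lone wild-type array was assumed to vary as the lines do. The number of arrays limits the precision of every value. The 3 arrays lay on 1 slide and were read in 1 scan, so no batch could be tested.

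The intensity values of each array were deposited as scanner output of Agilent Feature Extraction version 10.5.1.1, per the file headers, while the submitters' processing notes name version 9.1. Per the file headers, the processed signal of a spot is an intensity after subtraction of the background and correction of spatial trends, with a stand-in value where the spot did not exceed the background. The flags of each spot, another kind of column in the deposited files, mark signals well above background, saturation and outliers. The series' value table holds log2 values that the authors had quantile-normalized, to judge from the values: the sorted values of the 3 columns differed by under 0.001 throughout. Its columns had a median of 9.93 each and correlated with the log2 processed signal of the same array at r from 0.999 upward. They were not centred per probe and held no ratio, and the exact steps behind them are not given in the sources used here.

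Each array held 43803 spots used here, for 43603 different probes, besides 1417 control spots that were left out. The share of spots well above background was 68.8% on the wild-type array, 68.6% on that of line 4.4-1 and 67.9% on that of line 4.4-5. No spot was saturated, and 19, 33 and 16 spots with an outlier flag were left out on these arrays in that order. The log2 of the processed signal was taken, and each array's 75th percentile was subtracted. Spots of 1 probe were averaged. A gene was represented by its probe with the highest mean signal over the 3 arrays, among probes well above background on at least 1 array, which left 20292 genes. For 19 genes, probes disagreed in the sign of the change by over 0.5 each way, and these genes were not named. Probes were named through a RefSeq gene table of assembly TAIR10.1, with 34185 probes matched by accession, 1904 by gene name and 154 by the description in the array files. For 7359 probes no gene was found, and 1 probe matched several. Coordinates are those of the array files, whose headers name the build ath1:Jan2004. Where within its gene a probe lies was not analysed here.

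The lines were compared with the wild type by limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The fit has 1 residual degree of freedom per gene and leans on the variance shared among genes. A fixed size rule was applied beside it: a difference of at least 2-fold in the same direction in both lines. The fit was tested on simulated data for the same 20292 genes, with 200 genes changed by known folds and noise set by the difference between the lines. It recovered 0% of genes changed 2-fold, 7.33% of those changed 4-fold and 92.3% of those changed 16-fold, and 22.2% of its calls were false. The simulated arrays had no detection floor and no uneven background. Simulated noise gave 334.9 genes at least 2-fold apart in both lines on average. Comparisons of both lines with the same wild-type array share its chance values, so 100 sets of unchanged arrays were simulated, with normal noise whose size was set by the difference between the lines in 20 bins of mean signal. A probe not well above background on every array of 1 side has only a bound there. Its fold is given as at least N-fold, the mean of the bright side against the mean over the dim arrays of the higher of the lowest signal well above background and the probe's own signal. Those lowest signals were -6.18 on the wild-type array, -5.86 on that of line 4.4-1 and -5.78 on that of line 4.4-5. The limma test itself used the unbounded signals. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the other steps.

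The 25 gene lists, the rule for naming genes and the first set of alternatives below were fixed before the data were examined. The lists come from general knowledge of Arabidopsis and cover the DOF cluster, genes remembered from the study (not independent evidence), shoot branching, meristem and flowering, seed coat and mucilage, expansins and xyloglucan hydrolases, lignin and secondary wall, flavonoids and anthocyanin, glucosinolates, photosynthesis, the circadian clock, salicylate defence, jasmonate, abscisic acid with cold and drought, touch and rapid stress, heat shock, auxin, cytokinin, gibberellin, phosphate starvation, senescence and starvation, the cell cycle, root markers, seed markers and reference genes. Of 393 entries 383 were used, and 10 were left out because the name did not match the code (6 entries) or because no probe named the gene (4 entries). The median change of a list was placed among 10000 random lists of the same size matched on mean signal, as a description of these arrays. By this measure 13 of the 25 lists lay in the outer 2.5% on either side. Random lists draw genes singly, whereas members of a list may vary together, so such a place is not a test. Calls within a list were counted over all genes and adjusted over the list alone.

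The rule for naming genes takes the DOF cluster and the remembered genes, whatever their values. It then takes the 10 highest and the 10 lowest genes by the smaller change of the 2 lines, among called genes at least 2-fold apart in both lines and well above background on all 3 arrays. Places left empty were filled from genes at least 2-fold apart in both lines that did not pass the test, and these are named as such. Up to 5 genes per direction that were not well above background on 1 side follow, with the highest bounds. From each list with at least 3 members 2-fold apart in both lines in 1 direction, or with a median in the outer 2.5% of random lists on either side, up to 4 members are named. These are the members whose smaller change of the 2 lines was largest in the direction of the median. Members that went the other way are not named by this step, so those named need not be typical of their list. The 3 highest and 3 lowest genes between the lines and up to 3 root, seed and reference genes by mean signal complete the rule. A gene without a name keeps its code.

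The first set of alternatives was normexp background correction (offset 50) with quantile normalization, quantile scaling of the processed signal, a filter for probes well above background on all 3 arrays, no filter, the median of a gene's probes, the authors' value table, an intensity trend in eBayes, fold thresholds of 1.5 and 3, a joint threshold of test and fold, and each line left out. Added after seeing the data were signals below background raised to the lowest signal well above it, probes outside a middle band of the array (bins 5 to 14 of 19 bins of 28 rows), and noise in the simulation drawn from the differences between the lines.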

Results

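Transcript levels in the aerial parts of 2-week-old Arabidopsis seedlings were compared between wild-type Col-0 and 2 lines that overexpress the transcription factor AtDOF4.4. The series' title asks about shoot branching and the seed coat and names a neighbouring gene, AtDOF4.2, whereas the labels of both transgenic samples name AtDOF4.4. There was 1 array for the wild type and 1 for each line. Of the spots, between 67.9% and 68.8% per array were well above background. All levels are log2 signals relative to the array's 75th percentile, and changes are the line minus the wild type on that scale. Values with an SD are means of the 2 lines (n = 2), and the wild type had no replicate.

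The overexpressed gene was checked first, together with its neighbours on chromosome 4. AtDOF4.4 (AT4G21050, probe at chromosome 4, 11238998 to 11239057) stood at 4.57 in line 4.4-1 and 4.202 in line 4.4-5. In the wild type its probe was not well above background. The gene rose in both lines, and the mean of the lines was at least 1513-fold higher (limma adjusted p = 0.0217). AtDOF4.2 (AT4G21030, probe at chromosome 4, 11231923 to 11231982) likewise was not well above background in the wild type, and stood at 0.20 in line 4.4-1 and -0.23 in line 4.4-5. It rose by at least 71.6-fold (limma adjusted p = 0.0217). The transcripts of this gene family are similar in sequence, so whether the AtDOF4.2 probe measured its own transcript or that of AtDOF4.4 is uncertain, and probe sequences were not analysed here. AtDOF4.3 (AT4G21040, probe at chromosome 4, 11234830 to 11234889) and both probes of AtDOF4.5 (AT4G21080, starting at 11254622 and 11255186) were not well above background on any array.

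**Figure D1:**
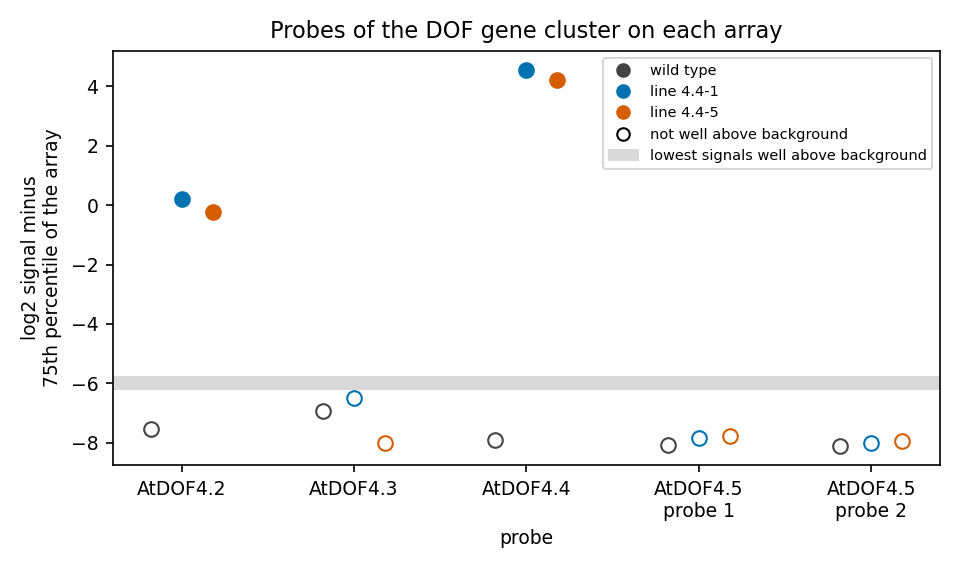
Level of each probe of the 4 DOF genes (y axis, log2 signal minus the array's 75th percentile) on the 3 arrays, with open circles for signals not well above background and a grey band for the lowest signals well above it. The AtDOF4.4 probe stands at 4.57 and 4.202 in the lines, and the AtDOF4.3 and AtDOF4.5 probes stay below the band on all 3 arrays.

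Among genes measured on all 3 arrays, 9 passed the test between the overexpressing lines and the wild type, with differences between 3.70-fold and 5.76-fold. The polyprenyl synthase gene cPT4 (AT5G58770) fell 5.76-fold, with a log2 change of -2.53 ± 0.02 (SD, n = 2). TZP (AT5G43630), a zinc knuckle protein gene with a part in light-dependent growth, fell 3.70-fold, and AT1G79120, of unknown function, fell 5.03-fold. Genes that rose were AT5G05965 of unknown function (5.58-fold), the oxygenase family gene AT2G38240 (4.98-fold), the methionine sulfoxide reductase gene MSRB8 (AT4G21840, 4.83-fold), the ferric reductase gene FRO5 (AT5G23990, 4.73-fold), AT4G33467 of unknown function (4.49-fold) and BT5 (AT4G37610, 3.90-fold), which encodes a protein with BTB and TAZ domains. Their limma adjusted p-values lay between 0.0280 for cPT4 and 0.0491 for TZP. For some of these genes the dim side was close to the detection floor. AT1G79120 stood at -5.775 and -5.571 in the lines, where the lowest signals well above background were -5.86 and -5.78. FRO5 and MSRB8 stood at -5.735 and -5.38 in the wild type, where that signal was -6.18. The probes of AT1G79120, FRO5 and MSRB8 lie in the middle band of the array, so their folds are uncertain. A fit restricted to probes well above background on all 3 arrays called 312 genes, of which 175 higher and 73 lower were also at least 2-fold apart in both lines.

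The remaining places in this ranking went to genes that were at least 2-fold apart in both lines without passing the test. Higher in line 4.4-1 and line 4.4-5, in this order, were the late embryogenesis abundant protein genes LEA7 (AT1G52690, 2.69 and 3.495), AT3G17520 (2.43 and 3.11) and GEA6 (AT2G40170, 2.35 and 2.93), and PAP85 (AT3G22640, 2.60 and 3.98), of the cupin family of seed storage proteins. Lower were HYH (AT3G17609), a transcription factor gene of light signalling (-1.97 and -2.14), and NdhT (AT4G09350), for a subunit of the chloroplast NDH complex (-1.79 and -2.56). So were the fatty acid elongation gene KCS2 (AT1G04220, -1.76 and -1.77), the carboxylesterase gene AT1G57590 (-2.09 and -2.61), the glycosyl hydrolase family gene AT5G24318 (-1.85 and -1.96), the DC1 domain gene AT2G19650 (-1.81 and -1.75) and the receptor-like protein gene RLP33 (AT3G05660, -1.80 and -1.72). HYH and AT5G24318 came closest to the threshold, with limma adjusted p-values of 0.0511 and 0.0531.

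By the mean of the lines, the largest differences named in each direction belonged to genes with a signal on 1 side only. The seed storage protein genes CRA1 (AT5G44120) and CRU3 (AT4G28520) rose by at least 249.3-fold and 132.7-fold, and the beta-glucosidase gene BGLU19 (AT3G21370) by at least 99.4-fold, each with a limma adjusted p of 0.0217. In the other direction, AT3G13760, of the DC1 domain family, fell by at least 7.85-fold, AT4G23330 by at least 6.48-fold and the cytochrome P450 gene CYP716A2 (AT5G36140) by at least 6.35-fold, with limma adjusted p-values from 0.0217 to 0.0238. AT3G09450 (at least 8.77-fold lower) and the oligopeptide transporter gene OPT8 (AT5G53520, at least 8.37-fold lower) did not pass the test. All 5 of these lower genes, and CRA1, BGLU19 and AtDOF4.2 among the higher ones, have probes within the middle band of the array (bins 5 to 14 of 19 bins of 28 rows), where spots above background on 1 array only were concentrated.

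In all, limma called 167 of 20292 genes, of which 74 rose and 93 fell. Only 9 of the called genes were well above background on all 3 arrays, while 67 were so in both lines but not in the wild type and 90 in the wild type but not in the lines. The 1 left had probes that disagreed in the sign of the change. Of those 90, 84 have probes in the middle band, a share of 93.3%, against 55.4% of all genes tested. Of the 9 called genes measured on all arrays 8 lie there, and of the 300 genes at least 2-fold lower in both lines 81.7%. The number of calls was not stable, since normexp with quantile normalization, quantile scaling, the unfiltered data and the authors' value table gave 0 calls each by limma (2498, 2159, 2773 and 2199 genes at an unadjusted p under 0.05, against 2175). The balance was not stable either, with 193 genes higher and 55 lower under an intensity trend, and 208 and 104 with probes well above background on all 3 arrays. In simulated data 22.2% of the calls made by the same fit were false. Those data had normal noise, no detection floor and no uneven background across the array. The share thus does not give the error rate of calls at background on 1 side.

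By size alone, 431 genes were at least 2-fold higher and 300 at least 2-fold lower in both lines than in the wild type. Among the genes well above background on all 3 arrays these numbers were 193 and 77. The wild-type array thus stood apart from both lines in 731 genes. The array of line 4.4-1 stood apart from both others in 264 genes, and that of line 4.4-5 in 390. The 2 lines went in opposite directions at 2-fold in 42 genes. Among the genes well above background on all 3 arrays, 28 and 112 genes stood apart in line 4.4-1 and line 4.4-5, and 2 went in opposite directions.

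The changes of the 2 lines went together across genes. Pearson's r was 0.73 and Spearman's rho 0.71 over 20292 genes, which are not independent replicates. Unchanged arrays that share 1 control gave 0.50 and 0.47 in simulation. The covariance was 0.33 against 0.13 in simulation, a difference of 0.21. Of the 431 higher and 300 lower genes, simulation with no effect gave 170.9 and 170.0, and independent lists of the same length would share 28.6 and 11.2. For genes well above background on all 3 arrays, r was 0.75 against 0.50 in simulation, and the 193 higher and 77 lower genes compare with 3.45 and 3.17 simulated. Only normal noise was simulated for these genes. If the differences between the lines have heavier tails than that, the simulated numbers are too low. The single wild-type array could not be split, so part of the excess may come from it.

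**Figure D2:**
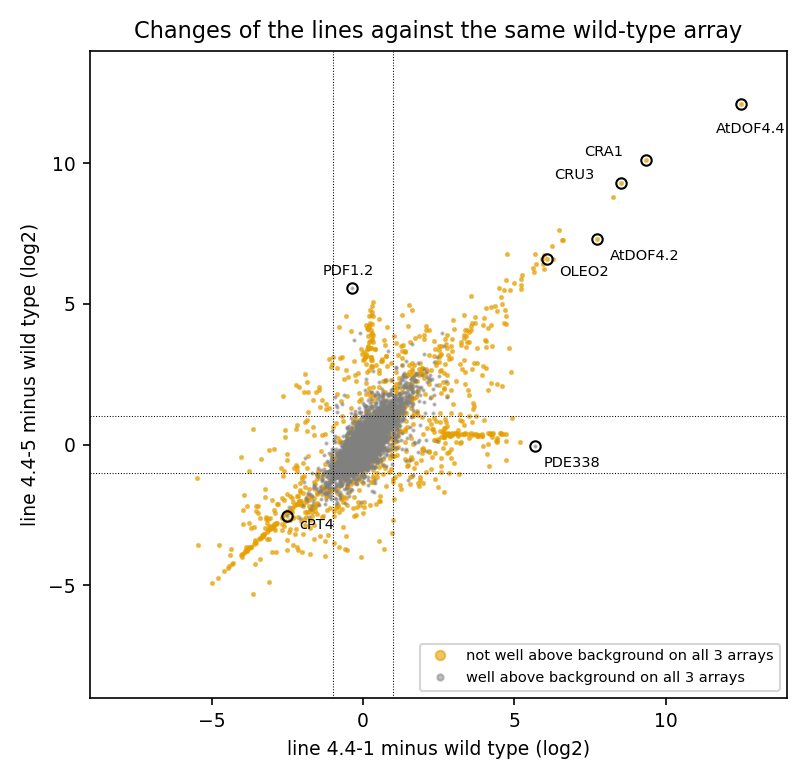
Log2 change of each of the 20292 genes in line 4.4-1 (x axis) and line 4.4-5 (y axis) against the same wild-type array, with dotted lines at 2-fold, grey points for genes well above background on all 3 arrays and orange points for the rest. AtDOF4.4, CRA1 and CRU3 lie highest in both lines, while PDE338 is apart in line 4.4-1 alone and PDF1.2 in line 4.4-5 alone.

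Line 4.4-1 differed from the wild type by at least 2-fold in 1062 genes, of which 667 were higher and 395 lower. Line 4.4-5 differed in 1442 genes, with 869 higher and 573 lower. Each of these comparisons sets 1 array against 1, with no replicate check and no test. With probes well above background on all 3 arrays the counts were 377 and 720.

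Between the lines, the genes for the plant defensins PDF1.2 (AT5G44420), PDF1.3 (AT2G26010) and PDF1.2c (AT5G44430), small antifungal proteins, were higher in line 4.4-5 than in line 4.4-1, by 5.94, 4.06 and 4.02 on the log2 scale. In line 4.4-1 all 3 were close to the wild type, with changes from -0.36 to -0.08. These defensin genes are near-identical copies, and their probes may not tell them apart. PDE338 (AT1G71720), for an RNA-binding protein, stood at 6.63 in line 4.4-1 against 0.94 in the wild type and 0.88 in line 4.4-5. The kinesin-related gene AT3G10180 and MRD1 (AT1G53480) were also lower in line 4.4-5 than in line 4.4-1, by log2 differences of -2.75 and -2.73. Altogether 324 genes were at least 2-fold higher and 358 at least 2-fold lower in line 4.4-5 than in line 4.4-1, with no test. With probes well above background on all 3 arrays, 185 genes were 2-fold apart between the lines in place of 682.

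Apart from the DOF cluster itself, genes of seed reserves and late embryogenesis showed the largest median difference among the gene lists. Of 12 measured seed markers, 6 rose, 6 did not pass the test over all genes, and 11 were at least 2-fold higher in both lines. Adjusted over the list alone, 11 passed. Only 2 of the 12 were well above background in the wild type, against 12 in both lines. Next to CRA1 and CRU3, the storage albumin gene SESA3 (AT4G27160) rose by at least 53.8-fold and the oil body protein gene OLEO2 (AT5G40420) by at least 19.8-fold (limma adjusted p of 0.0404 and 0.0217). The 2 markers measured in all plants were GEA6, at -3.51 in the wild type and -1.17 and -0.58 in the lines, and LEA4-5, whose changes were -0.17 and 0.45 (chosen after its values were seen). With probes well above background on all 3 arrays the list median was 1.39. The list's median change was 3.72 with genes at their bound, and its unbounded median of 5.56 lay above 100% of random lists.

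The list of senescence and starvation genes had a median change of 0.82, above 100% of random lists. Of its 13 measured members 0 rose, 1 fell and 12 did not pass the test over all genes. Adjusted over the list alone, 6 rose and 1 fell. DIN2 (AT3G60140), DIN10 (AT5G20250) and ASN1 (AT3G47340), which are known to respond to darkness and sugar shortage, were higher in line 4.4-1 and line 4.4-5 by 1.72 and 2.48, 1.51 and 1.76, and 1.39 and 1.60. SAG13 (AT2G29350) was higher by 1.62 and 1.36. The member that fell was SAG12, a protease gene of leaf senescence, by at least 2.79-fold. It was named after its value was seen.

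Defence and rapid stress genes tended to be higher in both lines, though 0 members of these lists passed the test over all genes. Among 19 salicylate-defence genes the median change was 0.70, and 6 members were at least 2-fold higher in both lines. PAD3 (AT3G26830), for the last step of camalexin synthesis, was higher by 2.31 and 1.99, GRX480 (AT1G28480) by 1.35 and 1.51, and WRKY38 (AT5G22570) by 1.26 and 1.51. PCR1 (AT1G14880) was at least 4.69-fold higher. Of 15 touch and rapid stress genes, with a median of 0.63, the xyloglucan hydrolase gene TCH4 (AT5G57560) was higher by 1.42 and 2.24, WRKY40 (AT1G80840) by 1.15 and 1.35, ERF6 (AT4G17490) by 1.01 and 1.40, and CML38 (AT1G76650) by 0.91 and 1.21. Both medians lay above 100% of random lists. Adjusted over the list alone, 7 and 5 members passed.

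The jasmonate list split between the lines. Its median over 22 genes was 0.23 (99.4th percentile of random lists), made up of 0.01 in line 4.4-1 and 0.34 in line 4.4-5. With probes outside the middle band the median was 0.0784, at percentile 74.7. No member passed the test, over all genes or adjusted over the list alone. In both lines 11 members were higher and 8 lower, of which 3 and 1 were at least 2-fold apart. AOC2 (AT3G25770), of jasmonate synthesis, was higher by 2.31 and 1.14, JAZ7 (AT2G34600) by 1.09 and 2.73 and VSP1 (AT5G24780) by 0.67 and 0.99, while LOX3 stood at -1.28 and -1.54 (named after its values were seen). The thionin gene THI2.1 (AT1G72260) was well above background in line 4.4-5 alone, at -3.88.

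Heat shock genes were lower. All 5 measured members were lower in both lines, with a median of -1.03, below 100% of random lists (percentile 0). None passed the test over all genes, and 3 fell when adjusted over the list alone. HSP90.1 (AT5G52640) stood at -1.09 and -1.15, HSP70 (AT3G12580) at -1.05 and -0.90, the heat shock factor gene HSFA2 (AT2G26150) at -0.91 and -1.16, and HSP18.2 (AT5G59720) at -0.53 and -1.53.

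Several lists of secondary metabolism had small downward medians that also lay in the outer 2.5% of random lists, and 0 of their members passed the test over all genes or adjusted over the list alone. For 21 lignin and secondary wall genes the median was -0.30, similar in both lines (-0.33 and -0.30), with FAH1 (AT4G36220) at -0.57 and -0.73, the laccase gene IRX12 (AT2G38080) at -0.52 and -0.74, 4CL1 (AT1G51680) at -0.52 and -0.77 and PAL4 (AT3G10340) at -0.47 and -0.44. For 19 glucosinolate genes it was -0.37, but -0.02 in line 4.4-1 (percentile 34.0) and -0.60 in line 4.4-5. The regulators MYB34 (AT5G60890, -0.70 and -0.83) and MYB28 (AT5G61420, -0.43 and -0.95) and the synthesis genes CYP79B2 (AT4G39950, -0.56 and -0.72) and SUR1 (AT2G20610, -0.44 and -0.62) were lower in both. Of the 19 glucosinolate genes, 10 were lower and 1 higher in both lines. The median of 17 flavonoid and anthocyanin genes was -0.29, and its sign differed between the lines, with 0.03 in line 4.4-1 (percentile 65.2) and -0.50 in line 4.4-5. With normexp and quantile normalization it was -0.174, at percentile 2.74. The chalcone isomerase gene TT5 (AT3G55120) stood at -0.57 and -0.50, UGT78D1 (AT1G30530) at -0.51 and -0.48, PAP1 (AT1G56650) at -0.39 and -0.70 and UGT78D2 (AT5G17050) at -0.37 and -0.95. Of the 17 flavonoid and anthocyanin genes, 7 were lower and 3 higher in both lines.

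For the processes in the study's title, list medians were small. In simulation the test recovered 0% of genes changed 2-fold and 7.33% of those changed 4-fold. The lack of calls in these lists therefore does not show that their genes were unchanged. BRC1, HB53 and CCD8 of the branching list changed more than its median, and their values are given under the other observations. Of 24 shoot branching genes measured, 0 passed the test and 0 were at least 2-fold apart in both lines, with a median of 0.08 at the 89.0th percentile. The sign differed between the lines, with -0.0760 in line 4.4-1 (percentile 11.97) and 0.23 in line 4.4-5 (99.5), and the median was -0.127 with the median probe of a gene. Seed coat and mucilage genes, 17 measured with 0 past the test, had a median of -0.18 (percentile 1.78, up to 27.8 under other settings), and the medians of the lines were -0.226 in line 4.4-1 and -0.279 in line 4.4-5. Their lowest members were the cellulose synthase gene CESA5 (AT5G09870, -1.12 and -0.93), TTG2 (AT2G37260, -0.73 in each line) and AP2 (AT4G36920, -0.64 and -0.51), and GL3 (AT5G41315) was above background in the wild type alone, at least 1.27-fold lower in the lines. Of 18 meristem and flowering genes, with a median of 0.19 at the 98.9th percentile (97.2 outside the middle band and 95.3 in line 4.4-1), 0 passed the test over all genes and 1 did adjusted over the list alone. The floral identity gene PI (AT5G20240) was higher by 1.48 and 1.39, SPL3 (AT2G33810) by 0.80 and 1.23 and SPL4 (AT1G53160) by 0.52 and 0.88, while AP1 (AT1G69120) was above background in line 4.4-1 alone. The genes remembered from the study were not past the test: STM (AT1G62360) differed by 0.01 ± 0.01, TFL1 (AT5G03840) by 0.30 ± 0.15, EXPA9 (AT5G02260) by 0.42 ± 0.01 and CYP83B1 (AT4G31500) by -0.50 ± 0.14 (SD, n = 2).

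The abscisic acid, cold and drought list had a median of -0.18 over 21 genes, with 0 calls over all genes. The 1 member that passed adjusted over the list alone went against the median: CBF1 (named after its values were seen) was higher by 1.78 and 1.91. The median lay at percentile 0.085, but the median was 0.03 with probes outside the middle band. The medians of the lines were -0.146 in line 4.4-1 and -0.0555 in line 4.4-5, the latter at percentile 12.7. LTI78 (AT5G52310) stood at -0.74 and -1.34, DREB1A (AT4G25480) at -0.56 and -1.01, COR15A (AT2G42540) at -0.46 and -1.83 and COR15B (AT2G42530) at -0.43 and -1.64. Medians within the middle 95% of random lists were those of photosynthesis (0.04, 21 genes), the circadian clock (-0.05, 19), expansins and xyloglucan hydrolases (0.03, 23), auxin (0.17, 13), cytokinin (-0.17, 10), gibberellin (0.03, 7), phosphate starvation (0.05, 8) and the cell cycle (0.08, 7). Outside the middle band the auxin median was 0.42, at percentile 99.9, and with the median probe of a gene the clock median was -0.168, at percentile 0.5. In line 4.4-1 alone the auxin (99.8), cytokinin (0.44) and gibberellin (0.87) medians were in the outer percentiles. In these lists 0 members passed the test over all genes, and only 1, of the auxin list, passed adjusted over its list alone.

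**Figure D3:**
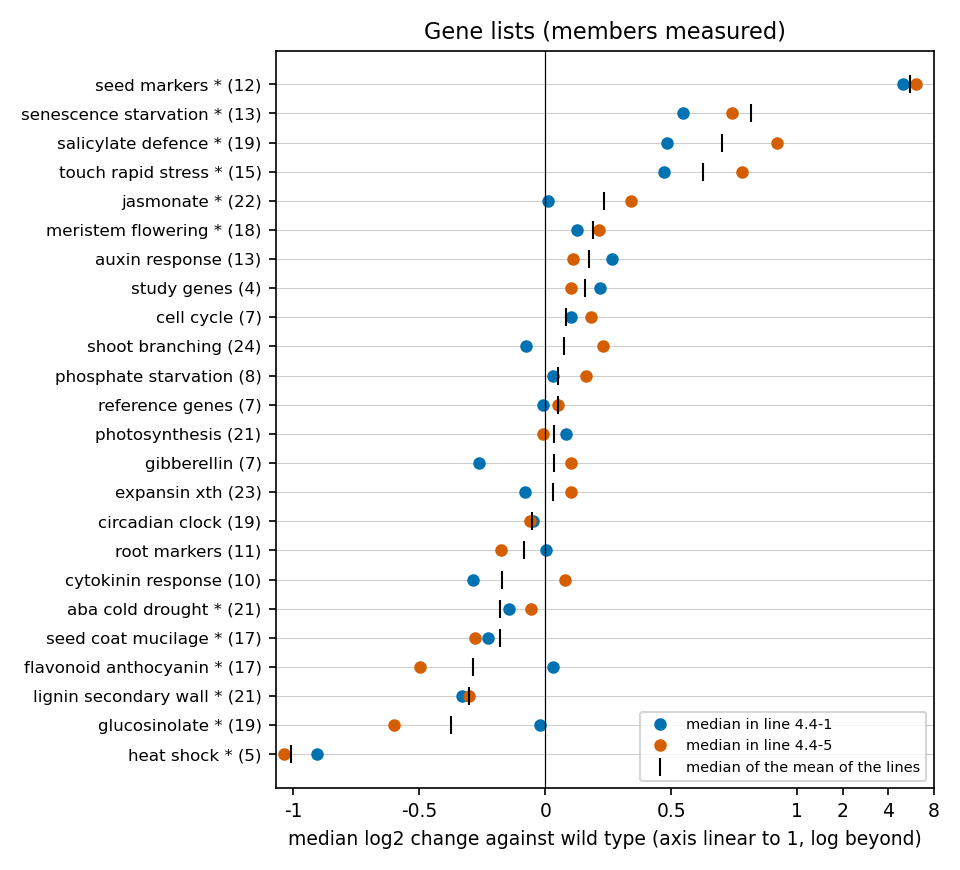
Median log2 change against the wild type (x axis, linear to 1 and logarithmic beyond) of each gene list except the DOF cluster in line 4.4-1 and line 4.4-5, with black ticks for the median of the lines' mean, an asterisk for medians in the outer 2.5% of random lists on either side, and the number of genes measured in brackets. Of the lists shown, seed markers stand farthest to the right at 5.56, which becomes 3.72 with genes at their bound, and heat shock genes farthest to the left at -1.03.

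Markers of another organ and reference genes were also looked at. The root markers had a median of -0.09 over 11 genes, with 0 calls. These 11 are the ones, of 14 listed, that had a usable probe well above background on at least 1 array. In the wild type all 11 were well above background, and 9 were so in both lines. Yet the samples are labelled as aerial parts. Whether they held root tissue was not tested. The root beta-glucosidase gene PYK10 (AT3G09260) was abundant on all arrays, at 5.01 in the wild type and 5.08 and 4.98 in the lines, and the endodermis genes CASP1 (AT2G36100) and CASP2 (AT3G11550) differed by -0.45 ± 0.31 and 0.34 ± 0.14 (SD, n = 2). Among 7 reference genes, with a median of 0.05 and 0 calls, UBQ10 (AT4G05320) differed by -0.03 ± 0.03, GAPC2 (AT1G13440) by -0.20 ± 0.09 and YLS8 (AT5G08290) by 0.05 ± 0.09. These 3 were bright, at 6.38, 5.74 and 4.015 in the wild type, and do not show how far dim genes vary. The sign for PYK10 and YLS8 was turned under the normexp and quantile settings, and that for UBQ10 with probes outside the middle band.

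Where a spot lay on the array bore on what was seen on 1 side only. Spots at least 2-fold brighter on 1 array and above background there alone numbered 382 for the wild type, 305 for line 4.4-1 and 272 for line 4.4-5. Of these, 93.5%, 94.4% and 94.5% lay in the middle band, which holds 53.3% of the probes. Negative control spots had a median intensity of 86.4, 86.3 and 81.2 inside this band and 57.2, 54.5 and 55.04 outside (permutation p = 2e-05 on each array, two-sided, the smallest that 100000 resamples can give).

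**Figure D4:**
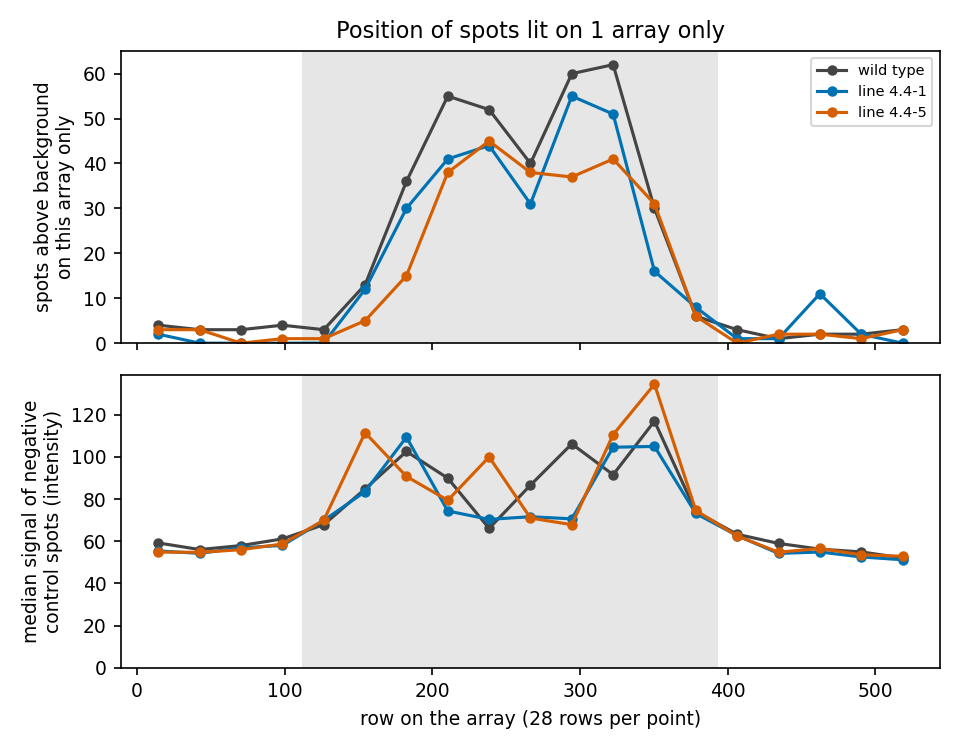
Number of spots above background on 1 array only (top) and median intensity of negative control spots (bottom) by row on the array, in bins of 28 rows, for the 3 arrays, with the middle band in grey. On the wild-type array 93.5% of such spots lie in the grey rows.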

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

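The test of uneven background was chosen only after its result was seen. Probes for which no gene was found were left out of every comparison above, and 37 of them were above background in both lines but not in the wild type and at least 2-fold higher there. The brightest by its bound lies at chromosome 2, 11278114 to 11278173 (build ath1:Jan2004), and was at least 88.8-fold higher in the lines. The next 2 lie at chromosome 4, 14089222 to 14089279 (at least 47.0-fold) and 13612345 to 13612401 (at least 46.3-fold). These positions fall beside the probe of CRU3 (14089479 to 14089538) and across that of SESA3 (13612327 to 13612386), both seed storage protein genes. Of the 37 probes, 30 lie in the middle band of the array and 7 outside. In the opposite direction, 136 such probes were above background in the wild type only.

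Spots above background on 1 array only were concentrated in the middle band of each array. A candidate explanation is an uneven background across the array, since the lowest share of such spots inside this band was 93.46%, on the wild-type array, against 53.34% of all probes, and negative control spots were brighter there on all 3 arrays. It applies to both directions of single-array signals and hence to genes measured in the wild type alone, of which 84 of 90 called ones lie there. Of the called genes above background in both lines only, 41 of 67 lie there, and of those above background on all 3 arrays, 8 of 9. Whether array position bears on the latter was not tested, and they cannot be taken as free of it. No biological explanation was tested for this pattern, and differences that rest on dim signals in this band stay open. The AtDOF4.2 difference did not rest on such signals. In the lines, its processed signals of 8647 and 6418 exceeded the highest mean signal of a negative control spot in the band (199.9 and 604). CRA1 (1.41 and 2.155) stood above AtDOF4.2 (0.20 and -0.23) in both lines, and BGLU19 stood at 0.19 and 0.72. Other genes of the band were not set beside the control spots here. Whether the AtDOF4.2 probe measured its own transcript stays uncertain.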

How the results depend on the processing

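The 3 alternatives on signals below background, array rows and simulated noise were chosen only after the data were seen. No paired analysis was possible because the groups share fewer than 2 replicate numbers, and no slide or scan block was run because all arrays share both. Leaving out 1 line leaves no residual degree of freedom, so those values carry no test. Signal over background limits the comparison, since genes at background on 1 side make up most calls.

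The number of genes called by limma (167) became 312 for probes well above background on all 3 arrays and 274 with low signals raised to the floor, and 0 under normexp with quantile normalization, quantile scaling, no filter and the authors' table. All 9 main calls tested under the stricter filter kept their call there. With low signals raised to the floor, only 95 of the 167 main calls kept theirs. The intensity trend (248) and the median of a gene's probes (118) stayed within 1.5 times in number, but only 70 of the 167 calls were shared with the trend, and the 74 higher and 93 lower calls became 193 and 55 there, 208 and 104 under the stricter filter, 156 and 118 with low signals raised and 148 and 56 outside the middle band. The weight that the fit gave to the variance shared among genes (prior degrees of freedom) differed between settings. It lay between 2.07 (no filter) and 2.53 (normexp) where there were 0 calls. It was 2.79 in the main fit and 6.96 under the stricter filter. A setting with 0 calls therefore need not have smaller differences. Whether this weight alone accounts for the changes in calls was not tested.

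Genes at least 2-fold apart in both lines (431 higher, 300 lower) numbered 193 and 77 for probes well above background on all 3 arrays, 188 and 65 outside the middle band (where fewer genes were tested), 908 and 672 at 1.5-fold and 215 and 187 at 3-fold. The lower genes numbered 186 with low signals raised to the floor. With 1 line left out, 667 to 869 were higher and 395 to 573 lower.

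For line 4.4-1 (1062 genes), line 4.4-5 (1442) and the lines against each other (682), the counts were 377, 720 and 185 for probes well above background on all 3 arrays, 306, 534 and 111 outside the middle band, 2136, 3415 and 1543 at 1.5-fold, and 625, 756 and 402 at 3-fold. The last of these comparisons gave 1108 without a filter and 423 with low signals raised. The correlation between the lines (0.73) was 0.755 with normexp, 0.716 with quantile scaling, 0.753 for probes well above background on all 3 arrays, 0.707 without a filter, 0.716 with the median probe, 0.837 outside the middle band and 0.776 with low signals raised. With resampled noise its simulated value was 0.498.

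AtDOF4.4 and AtDOF4.2 stayed higher under every alternative that could be run, but were no longer past the threshold with normexp (log2 changes of 10.47 and 5.59, adjusted p = 0.0978), quantile scaling (12.21 and 7.42, 0.0512), no filter (12.29 and 7.52, 0.0766) and the authors' table (12.25 and 7.36, 0.0613). These log2 changes are against a wild-type signal at background. Under the filter for all 3 arrays both genes drop out.

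The cause of reversed values was not tested. Among lists in the outer 2.5% of random lists, the flavonoid median was 0.0306 without line 4.4-5 and -0.499 without line 4.4-1, and the abscisic acid median was 0.0291 outside the middle band. Among the other lists, the medians of shoot branching, expansins, photosynthesis, gibberellin, phosphate starvation and reference genes changed sign under at least 1 setting with all arrays, and those of cytokinin and root markers did with 1 line left out. Shoot branching was -0.127 with the median probe and -0.0115 outside the middle band. STM was -0.0701 with the median probe. PYK10 was -0.136 with normexp, -0.00605 with quantile scaling and -0.0102 with the authors' table, YLS8 -0.13, -0.0455 and -0.0452, and UBQ10 0.0603 outside the middle band. Genes that differ between the lines depend on the line kept. With line 4.4-1 left out, or else line 4.4-5, the change was -0.0568 or 5.685 for PDE338, -1.10 or 1.65 for AT3G10180, -1.25 or 1.47 for MRD1, 5.57 or -0.36 for PDF1.2, 3.98 or -0.082 for PDF1.3, 3.72 or -0.29 for PDF1.2c, -0.026 or 0.0752 for PYK10 and 0.116 or -0.00998 for YLS8. Over 761 values of 92 named genes under the settings with a test, 589 kept side and direction, 84 lost the call and 80 gained it. Of 199 list medians, 173 moved by no more than the SD between the medians of the lines.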

Other observations

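Of the tests below, only that of a common source for the salicylate-defence genes was chosen after the result was seen. The tests of seed material and of a carbon shortage were set before the genes they use were seen, but after others had been. Those were LEA7, PAP85 and GEA6 for the former, and HYH and TZP for the latter, so neither test was chosen blind to its pattern. Beyond the genes named above, a few list members differed from their lists. In the shoot branching list, BRC1, the branching repressor, was higher by 0.77 and 0.88 in line 4.4-1 and line 4.4-5, and HB53, which is known to act with it in buds, by 0.91 and 1.60. The strigolactone synthesis gene CCD8 was lower, at -0.87 and -0.73. None of the 3 passed the test (limma adjusted p of 0.249, 0.371 and 0.270), and they were chosen after their values were seen. The light-harvesting gene LHCB2.1 was lower, at -1.18 and -1.69 (limma adjusted p = 0.230), while the photosynthesis list was near 0.

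Of the seed-stage genes measured on all arrays, LEA7, PAP85 and GEA6 were higher in the lines without passing the test, while LEA4-5 was near the wild type. A general abscisic acid or dehydration response is argued against only as far as the mixed list of abscisic acid, cold and drought genes can show it. The median of that list was at most -0.0555 in either line, with an SD of 0.70 between members, far below the change of the seed genes. Outside the middle band it was 0.0291. A response of the abscisic acid genes alone was not tested. One source for both the seed and the salicylate-defence genes cannot be told apart: the ratio of the amounts above wild type (line 4.4-5 over line 4.4-1, log2) differed from that of 7 storage genes by -0.664 over the 17 defence genes higher in both lines (exact permutation p = 0.290, two-sided, over genes, which are not independent), and by -1.01 (p = 0.0117) over only the 6 that were 2-fold higher in both. The 6 were chosen by the same changes that make up the ratio, so their p-value cannot decide the question. An embryo programme switched on through its known regulators stays open: 0 of LEC1, LEC2, FUS3 and ABI3 were above background in both lines and 2-fold higher, yet LEC1 and FUS3 each had a signal in 1 line and in the wild type. Seeds or embryos in the sampled material of the lines stay open too: the median of 7 storage protein genes at their bounds was at least 3.41 in the lower line, which such material would need, but this does not separate it from an effect of AtDOF4.4, which was not tested.

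HYH and TZP, which are known from light responses, were lower in both lines, HYH without passing the test, and no list or enrichment was tested for this theme. Harvest at another time of day cannot be told apart: morning minus evening clock genes gave -0.72 in line 4.4-1 and -0.28 in line 4.4-5, between the limits set in advance. A shortage of carbon in the plants of the lines stays open: the median of 5 dark- and starvation-induced genes was 1.39 in the lower line and 1.76 in the other, but these genes also respond to darkness and senescence and do not single out this cause. Whether such a state came from the transgene, the handling of the plants or the single wild-type sample was not tested.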
